A study of Mus musculus with 12 samples.

How the data were processed

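Total RNA from 12 mouse placentas of strain 129S6/SvEvTac at embryonic day 12.5 was sequenced, per the labels. Female littermates had been randomised at weaning to an iron deficient (ID) or an iron adequate (IA) diet and stayed on it until their placentas were taken. The labels' protocols name RNAlater, the Qiagen RNeasy plus mini kit and the NEBNext Ultra RNA library kit. The titles divide the libraries by diet and fetal sex into 4 groups of 3. The labels do not say which placentas share a dam or a litter, so each p-value measures the spread between these samples and the placentas were treated as independent.

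The deposited table holds whole-number read counts per gene, made by the authors with featureCounts, per the submitters' processing notes. Those notes also name bcl2fastq 2.17, Trimmomatic 0.39, STAR 2.7.2b and the genome build GRCm38.p6. The version of featureCounts, the annotation release and whether counting used strand are not given in the sources used here. Each of the 12 columns was mapped to 1 sample. The table lists 55471 genes, of which 22677 had no count in any library. Symbols, positions, exonic lengths and biotypes were taken from GENCODE M21, on GRCm38. Without the version number 55230 identifiers matched it, and 241 did not.

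Library totals ranged from 12401000 to 21442930 counts. Genes were filtered with filterByExpr on the 4 groups, which left 17973, and totals were scaled by TMM factors. CPM values in the text use the scaled totals, except that values of Xist, Ddx3y, Afp, Tfrc and Tpbpa given for single libraries or as a range, and the Afp means, use unscaled totals. The common dispersion of 0.0156 gave a biological coefficient of variation of 12.5%. All 12 libraries entered a single fit with 4 group means and the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. From it came the diet difference averaged over the sexes, the diet difference in females and in males, the diet by sex interaction and the sex difference averaged over the diets. The interaction is the male diet difference minus the female one. Each p was adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Errors of fold changes are standard errors (SE) from that fit, and errors of CPM are standard deviations (SD).

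Gene lists were written before the data were examined. They cover iron handling, heme, hypoxia, cell types of the placenta and its neighbouring tissues, metabolism, hormones, stress, immunity, growth and RNA quality. The 39 lists hold 1094 distinct genes, of which 1060 were in the table under that symbol and 943 were tested. For diet 36 lists had the 5 tested members required, and lymphocytes did not. Lists of Y-linked and X-linked genes were for the sex contrast only, and the Y-linked list had too few tested members for a list test. Each list was tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with a correlation estimated for each list, and fry, were run beside it. Camera asks whether the members differ from the other genes in the same libraries, and the preset correlation gives smaller p-values where members move together from placenta to placenta. Counts of members "over the list alone" use the edgeR p adjusted within the list.

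A fixed rule chose the genes named. A named gene had a symbol that is not a predicted or clone name and a mean of at least 1 CPM. For the averaged diet contrast the rule allowed up to 12 genes past the threshold in each direction with the same sign in both sexes. Within a sex it allowed up to 10 in each direction whose 3 ID libraries all lay on the same side of the 3 IA libraries. For the interaction and for sex it allowed up to 8 in each direction. Where fewer than 6 genes passed, it took the 10 with the smallest unadjusted p. That held for every contrast except sex, so the limits of 12 and 10 and their conditions were not used. The rule added up to 4 members with the smallest p of each list past the threshold or with 3 members past it. It also added 29 genes of iron, oxygen, transport and placental hormones whatever their values. Further members of lists, such as those past the threshold only over the list alone, were chosen after their values were seen.

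The scripts were tested on simulated data: counts drawn from the means and library sizes of these samples, with about 67 genes changed at each fold size. For the averaged diet contrast 17767 simulated genes were tested, and 65.7%, 92.5% and 97% of the genes changed by a fold of 1.5, 2 and 3 were recovered, with 13 false calls. For diet in females the shares were 40.3%, 74.6% and 92.4% with 10 false calls, and for diet in males 47.8%, 73.1% and 89.4% with 9, over the same number of genes. For the interaction they were 16.4%, 50.7% and 83.3% with 8 false calls over 17778 genes. For sex they were 67.2%, 86.6% and 100% with 9 false calls over 17796 genes. Each simulated gene had the same spread in all libraries, while the limma sample weights of the real ones ran from 0.281 to 1.83. These shares may therefore not hold for the real libraries. In the list test 1 of 36 lists, nuclear oxidative phosphorylation, was lowered by 10%. It was the only list called, with the preset and with the estimated correlation. Each gene was drawn independently, so this does not show how often camera calls lists whose members move together. In the real samples the estimated correlation of that list was 0.52.

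The alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom with and without sample quality weights, size factors of DESeq2 within edgeR, 2 other filters on low counts, removal of hemoglobin and mitochondrial genes before scaling, blocks on the replicate number, an additive model, 1 surrogate variable from sva 3.50.0, each sex fitted alone, and each library left out in turn. Added after the data were examined were fits without 2 or 3 libraries, a correction on exonic length and GC content, the share of ribosomal repeat counts as a covariate, and the list tests of the interaction and of sex, with all their alternatives. The libraries left out together were female IA 1 and male ID 1, which lay apart on the first principal component, and then also male IA 1, which had a low limma sample weight. Comparisons of a quality measure between the diets used an exact permutation test over all divisions of the 12 libraries into 6 and 6.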

Results

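Gene counts were analysed from 12 placentas at embryonic day 12.5, 3 from each group of female ID, male ID, female IA and male IA. Library totals were 18066237, 21442930 and 19278818 counts in female ID 1 to 3 and 12401000, 15819695 and 14974076 in male ID 1 to 3. They were 14695792, 18356201 and 20952360 counts in female IA 1 to 3 and 17935628, 18229619 and 16403035 in male IA 1 to 3. The sex labels matched the counts. Xist was at 49.4 to 122.5 CPM in libraries labelled female and at 0.887 to 2.804 CPM in those labelled male, while Ddx3y was at most 0.7627 CPM in the former and at least 50.6 CPM in the latter. The first principal component held 29.5% of the variance. Its mean was -12.58 ± 16.06 (SD, n = 6) in ID and 12.58 ± 23.22 (SD, n = 6) in IA placentas, with an exact permutation p = 0.05195. Female IA 1, at -31.5, and male ID 1, at -43.7, lay furthest on the ID side. Ribosomal repeat transcripts were 1.65% ± 0.839 of counts in ID and 1.134% ± 0.3745 in IA placentas (SD, n = 6, exact permutation p = 0.2208), and were highest in male ID 1 (2.785%), male ID 3 (2.593%) and female IA 1 (1.783%).

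The first question, after the series title, was what maternal iron deficiency changed in the placenta, averaged over fetal sex. Transcripts of the iron uptake genes Tfrc and Slc11a2 rose. The transferrin receptor Tfrc (ENSMUSG00000022797.16, chromosome 16, 32608920 to 32632794, GRCm38) was at 1704 ± 188 CPM in ID and 784 ± 140 CPM in IA placentas (SD, n = 6), a log2 fold change of 1.12 ± 0.12 (SE, edgeR adjusted p = 0.00428) or 2.18-fold. The divalent metal transporter Slc11a2 (ENSMUSG00000023030.16, chromosome 15, 100387898 to 100425072) rose from 64.2 ± 4.37 to 89.2 ± 4.58 CPM, by 0.48 ± 0.053 on the log2 scale (edgeR adjusted p = 0.00428). Both transcripts carry iron-responsive elements in known isoforms, and low iron is known to stabilise Tfrc mRNA. Storage and export genes did not pass: the ferritins Fth1 (-0.066 ± 0.070) and Ftl1 (-0.19 ± 0.075), the exporter Slc40a1 (0.046 ± 0.063) and its regulator Hamp (-0.006 ± 0.20, near 1 CPM). Nor did Heph (0.53 ± 0.22), Cybrd1 (0.30 ± 0.22), Slc39a14 (-0.024 ± 0.066), Trf (0.74 ± 0.43), Hmox1 (-0.15 ± 0.065) or Alas2 (0.24 ± 0.10).

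Of the 35 tested members of the iron list, 22 were positive and 13 negative, with a median log2 fold change of 0.046 (camera adjusted p = 0.037, or 0.564 with an estimated correlation). Over all genes 2 rose, and over the list alone 4 did: Tfrc, Slc11a2, the mitochondrial importer Slc25a37 (0.37 ± 0.089) and Slc39a8 (0.50 ± 0.15). The list lost its camera call without female ID 1 (adjusted p = 0.102) and without male IA 3 (0.0817), within 0.00616 to 0.564 over 20 alternatives, and also with 3 libraries left out (0.106), after the length and GC correction (0.178) and with the ribosomal repeat covariate (0.0506). The genes of hepcidin and BMP signalling (median 0.009, mean -0.005), heme synthesis (0.046) and iron-sulfur cluster assembly (-0.052) did not pass as lists (camera adjusted p = 0.727, 0.18 and 0.0665). Over the list alone, Cpox of heme synthesis rose (0.45 ± 0.084) and Isca2 of cluster assembly fell (-0.37 ± 0.079).

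**Figure D1:**
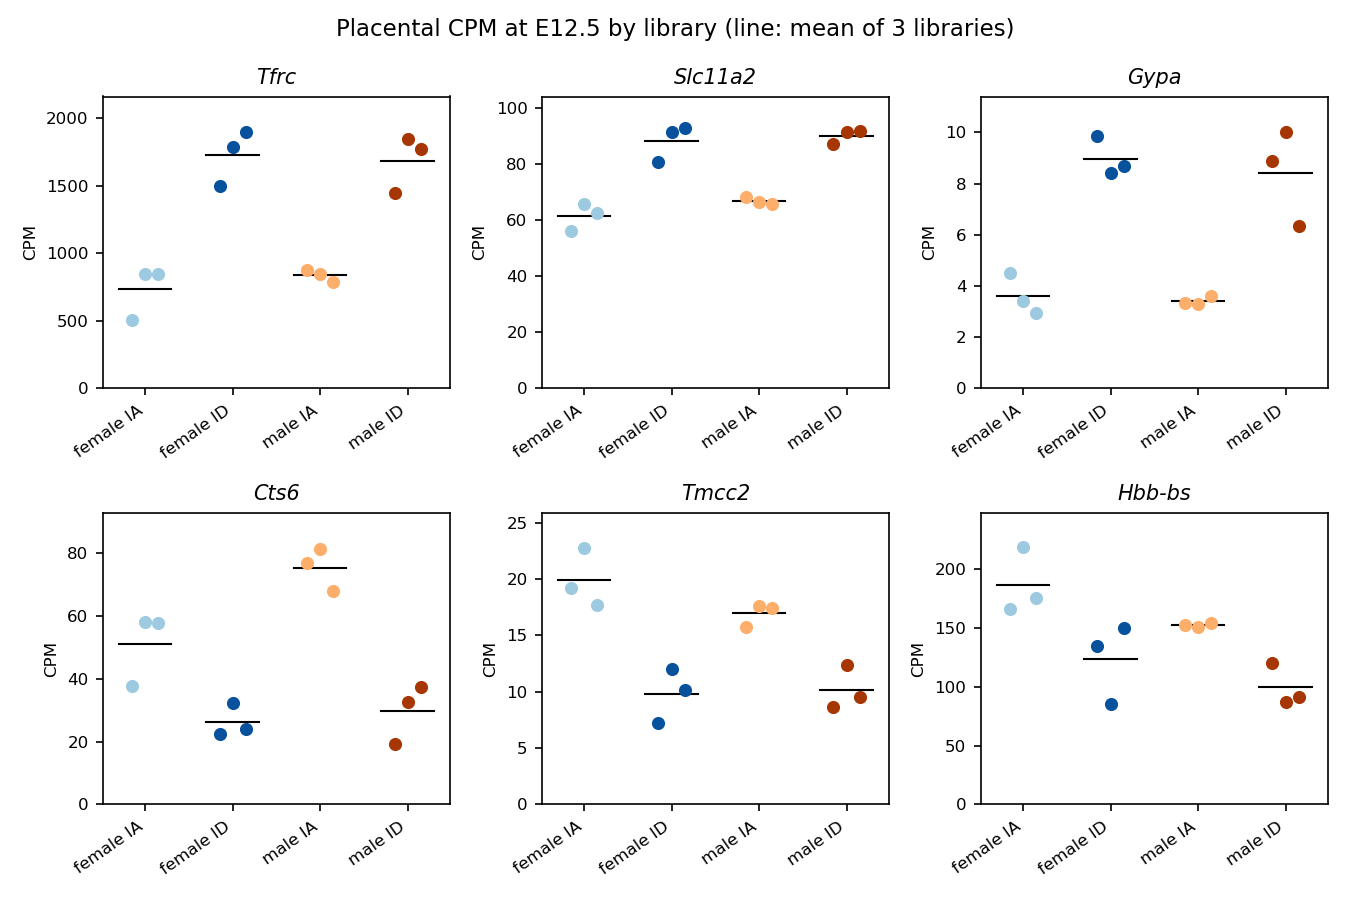
CPM of 6 genes in each of the 12 placentas, with points for libraries, a line for the mean of 3 and CPM on each vertical axis from 0. For Tfrc, Slc11a2, Gypa, Cts6 and Tmcc2 all 6 ID placentas lie beyond all 6 IA placentas; Hbb-bs did not pass the test.

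Erythroid genes moved in opposite directions. The red cell membrane gene Gypa (ENSMUSG00000051839.7, chromosome 8, 80493781 to 80510542) rose from 3.51 ± 0.534 CPM in IA to 8.70 ± 1.31 CPM in ID placentas (SD, n = 6; log2 fold change 1.32 ± 0.14, SE, edgeR adjusted p = 0.00428). Tmcc2 (ENSMUSG00000042066.16, chromosome 1, 132356315 to 132391281), placed on the erythroid list beforehand, fell from 18.4 ± 2.40 to 10 ± 2 CPM, by -0.87 ± 0.13 (edgeR adjusted p = 0.0418). Hemgn (2.03 ± 0.33, edgeR adjusted p = 0.0715) and Rhag (0.94 ± 0.17, 0.127) did not pass over all genes. The adult globins Hbb-bs (-0.61 ± 0.13, edgeR adjusted p = 0.137) and Hba-a1 (-0.54 ± 0.14, 0.16) did not pass either, and their shares are uncertain because Hbb-bs and Hbb-bt, and Hba-a1 and Hba-a2, are near-identical. Over the list alone 13 of 32 members rose, among them Gypa, Hemgn, Rhag and Klf1 (1.076 ± 0.28), and 7 fell, among them Tmcc2, Bpgm (-0.40 ± 0.077), Hbb-bs and Hba-a2 (-0.66 ± 0.14). The embryonic globins divided as well, with Hbb-bh1 higher (0.78 ± 0.18) and Hbb-y lower (-0.43 ± 0.15) over the list alone. Heme is known to drive globin synthesis, and iron deficiency is known to restrict it.

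As a list, erythroid genes had a median of 0.26 (camera adjusted p = 0.037, or 0.699 with an estimated correlation). The camera call was lost without female ID 1 (adjusted p = 0.212), male ID 1 (0.0662), male ID 2 (0.248), female IA 1 (0.0987), female IA 2 (0.0507), female IA 3 (0.0551) or male IA 2 (0.189), within 0.000289 to 0.699 over 20 alternatives, and with 2 (0.143) or 3 libraries left out (0.187). Tmcc2 lost its edgeR call without female ID 1 (adjusted p = 0.0639), female ID 3 (0.146), male ID 1 (0.181), male ID 3 (0.11), female IA 2 (0.155), female IA 3 (0.0867), male IA 2 (0.158) or male IA 3 (0.219). It also lost it with 1 surrogate variable (edgeR adjusted p = 0.0684) and the ribosomal repeat covariate (0.449), within 7.75e-08 to 0.449 over 27 alternatives. Its log2 fold change was -0.82 and -0.80 in these fits and -0.96 to -0.77 over the 27. Tmcc2 also did not pass in limma with the replicate block within diet as a random effect. Tfrc, Slc11a2 and Gypa passed in all 27, at 1.02 to 1.26, 0.43 to 0.52 and 1.25 to 1.43 on the log2 scale.

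Of the trophoblast genes only Cts6 passed over all genes. The cathepsin Cts6 (ENSMUSG00000021441.4, chromosome 13, 61195132 to 61203410) fell from 63.2 ± 15.8 CPM in IA to 27.9 ± 7.10 CPM in ID placentas (SD, n = 6), by -1.15 ± 0.16 on the log2 scale (SE, edgeR adjusted p = 0.027). It belongs to a cluster of placental cathepsins, so reads may have been shared. Other giant cell genes fell over the list alone, which held 22 tested members: Ctsq (-0.56 ± 0.14), Adm (-0.49 ± 0.12) and Lepr (-0.38 ± 0.11). Among 33 spongiotrophoblast and glycogen trophoblast genes 6 fell over the list alone, including Tpbpa (from 8620 ± 1680 to 5702 ± 1188 CPM, -0.60 ± 0.16), Tpbpb (-0.88 ± 0.22), Ceacam11 (-0.91 ± 0.22) and Ceacam12 (-1.01 ± 0.26). None of the 6 passed over all genes, and the Ceacam and Prl families share similar sequences. The lactogen Prl3b1 (-0.25 ± 0.11), the labyrinth gene Synb (-0.011 ± 0.15) and the labyrinth list (median -0.004, camera adjusted p = 0.727) did not pass.

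The spongiotrophoblast list had a median of -0.24 with 27 of 33 members negative (camera adjusted p = 0.00022), and the giant cell list -0.11 with 17 of 22 negative (0.00132), each at 0.564 with an estimated correlation. The giant cell call was lost without male IA 1 (camera adjusted p = 0.0613), within 1.07e-05 to 0.564 over 20 alternatives, and both calls were lost with 3 libraries left out (0.106 for giant cells, 0.0572 for spongiotrophoblast). The length and GC correction also ended the giant cell call (0.104). Cts6 lost its edgeR call without female ID 1 (adjusted p = 0.0893), female ID 3 (0.121), male ID 2 (0.08), female IA 2 (0.111), female IA 3 (0.0867), male IA 2 (0.107) or male IA 3 (0.0788), and with the ribosomal repeat covariate (0.431), within 4.14e-14 to 0.431 over 27 alternatives. Its log2 fold change was -1.001 with that covariate and -1.25 to -0.997 over the 27. Cts6 also did not pass in limma with the replicate block within diet as a random effect.

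Visceral endoderm and yolk sac genes had the largest median, 0.65, with 25 of 28 members positive (camera adjusted p = 0.000706, or 0.63 with an estimated correlation), for example Dab2 (0.60 ± 0.20) and Hnf1b (0.46 ± 0.15), while Rhox5 was negative (-0.22 ± 0.075). No member passed the edgeR test over the list alone. Afp, made by yolk sac endoderm and not by trophoblast, ranged from 336.7 to 4615 CPM between libraries with means of 2573 ± 1589 in ID and 1666 ± 1116 in IA (SD, n = 6, exact permutation p = 0.2792). Mesenchyme and pericyte genes had 20 of 25 members positive, such as Col5a1 (0.48 ± 0.18) and Col6a1 (0.45 ± 0.14), and a median of 0.18 (camera adjusted p = 0.00124, or 0.564 with an estimated correlation). Among 26 myeloid genes (median 0.16, camera adjusted p = 0.012, or 0.564 with an estimated correlation), Mrc1 (0.59 ± 0.12) and Laptm5 (0.57 ± 0.12) rose over the list alone, and Cd68 was negative (-0.36 ± 0.11). The camera call was lost without female ID 3 (adjusted p = 0.0604) or male IA 1 (0.0589) for myeloid genes, within 0.00228 to 0.564 over 20 alternatives. It was lost without male IA 1 (0.0634) for yolk sac genes, within 4.19e-09 to 0.63. With 3 libraries left out both calls ended (0.209 and 0.19), as they did with the ribosomal repeat covariate (0.093 and 0.0943), when the yolk sac median was at its lowest, 0.13. The myeloid call also ended with 2 libraries left out (camera adjusted p = 0.0634).

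Other cell type lists did not pass: uterine natural killer cells (median -0.14, camera adjusted p = 0.0795), smooth muscle (-0.10, 0.24), neutrophils (-0.15, 0.272), endothelium (-0.039, 0.439), decidual stroma (-0.027, with the test upward, 0.969) and embryonic neural and muscle tissue (-0.30 with a mean of -0.008, 0.723). Over the list alone Timp3 of decidual stroma rose (0.32 ± 0.067), Smtn of smooth muscle fell (-0.19 ± 0.047), and in embryonic tissue 2 genes rose and 3 fell, with Nefl at 1.16 ± 0.27 and Tubb3 at -0.33 ± 0.072. Angiogenic factors (median 0.033, camera adjusted p = 0.433) and renin-angiotensin genes (0.084, 0.36) did not pass, nor did Vegfa (-0.14 ± 0.10), Flt1 (0.016 ± 0.18) or Pgf (-0.10 ± 0.10).

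Mitochondrial respiratory genes were lower and cholesterol synthesis genes higher by small amounts. Of 75 nuclear oxidative phosphorylation genes 64 were negative, with a median of -0.125 (camera adjusted p = 8.25e-08, or 0.564 with an estimated correlation). Ndufs8 fell over the list alone (-0.30 ± 0.063), and Ndufa7 (-0.30 ± 0.077) did not pass. Mitochondrially encoded transcripts had 13 of 15 members negative and a median of -0.17 (camera adjusted p = 0.00665, or 0.63 with an estimated correlation), for example mt-Nd2 (-0.23 ± 0.12) and mt-Nd3 (-0.25 ± 0.10). Their share of counts was 2.187% ± 0.1547 in ID and 2.376% ± 0.3271 in IA placentas (SD, n = 6, exact permutation p = 0.2143). That list lost its camera call without male ID 2 (adjusted p = 0.061), within 3.02e-05 to 0.63 over 19 alternatives, and its median turned to 0.026 after the length and GC correction (0.528). Of 25 cholesterol synthesis genes 24 were positive, with a median of 0.16 (camera adjusted p = 6.21e-06, or 0.564 with an estimated correlation), and Insig1 rose over the list alone (0.25 ± 0.057) while Mvd (0.24 ± 0.079) did not pass. Several respiratory subunits carry iron-sulfur clusters or heme, and Ndufs8 is among them.

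Of 22 glycogen genes 17 were positive, with a median of 0.10 (camera adjusted p = 0.00665, or 0.564 with an estimated correlation), and Pygb (0.35 ± 0.098), Pgm1 (0.22 ± 0.065) and Phka1 (0.26 ± 0.075) rose over the list alone. Of 53 nutrient transporters 39 were positive, with a median of 0.071 (camera adjusted p = 0.00786, or 0.564 with an estimated correlation). Over that list alone Slc2a3 (0.69 ± 0.17) and the manganese exporter Slc30a10 (0.97 ± 0.25) rose, and the lipid carriers Fabp4 (-0.63 ± 0.15) and Mfsd2a (-0.33 ± 0.059) fell. Slc2a1 (0.099 ± 0.068), Slc38a2 (0.13 ± 0.079) and Slc38a4 (0.074 ± 0.089) did not pass. The transporter call ended after the length and GC correction (camera adjusted p = 0.119) and with the ribosomal repeat covariate (0.0604), within 0.00206 to 0.564 over 20 alternatives. Hypoxia targets did not pass as a list (median 0.074, camera adjusted p = 0.0585). Over that list alone 6 rose, among them Pgk1 (0.22 ± 0.056), Ldha (0.20 ± 0.064) and Ak4 (0.39 ± 0.10), and 3 fell, Adm, Angptl4 (-0.34 ± 0.10) and Bnip3l (-0.20 ± 0.056).

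Interferon response genes were lower, with 26 of 31 negative and a median of -0.16 (camera adjusted p = 0.000504, or 0.564 with an estimated correlation). Over the list alone 5 fell, including Isg15 (-0.44 ± 0.12), Xaf1 (-0.34 ± 0.093), Ifi35 (-0.31 ± 0.078) and Mx2 (-0.81 ± 0.24). Higher were proliferation (median 0.081, 27 of 38 positive, camera adjusted p = 0.00331), chromatin dioxygenases (0.12, 20 of 26 positive, 0.00665), and insulin-like growth factor and mTOR signalling (0.12, 24 of 30 positive, 0.00991), each at 0.564 with an estimated correlation. Mcm6 (0.19 ± 0.054) and Cdt1 (0.22 ± 0.059) rose and Ccne2 (-0.20 ± 0.049) fell over the proliferation list alone. The dioxygenase genes Tet3 (0.23 ± 0.092) and Kdm2b (0.24 ± 0.098), Rptor (0.26 ± 0.092), Igf2 (0.32 ± 0.13) and the binding protein Igfbp1 (1.89 ± 0.53, with 18.6 ± 14.4 against 5.09 ± 3.19 CPM) did not pass. Proliferation lost its camera call with 3 libraries left out (adjusted p = 0.0758), dioxygenases after the length and GC correction (0.256), and growth factor signalling with that correction (0.211) and the ribosomal repeat covariate (0.149), within 0.000151 to 0.564, 8.51e-05 to 0.564 and 0.00242 to 0.564 over 20 alternatives each.

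The remaining lists did not pass camera. Steroid hormone synthesis had a median of -0.10 (adjusted p = 0.0527), with Hsd11b1 (-0.94 ± 0.22), Hsd3b6 (-0.53 ± 0.12), Hsd17b2 (-0.24 ± 0.058) and Srd5a1 (-0.52 ± 0.15) lower over the list alone. The antioxidant response had -0.057 (camera adjusted p = 0.236), with Mt2 (-0.34 ± 0.088), Nqo1 (-0.37 ± 0.096) and Prdx4 (-0.35 ± 0.092) lower over the list alone. Imprinted genes had -0.023 (camera adjusted p = 0.463), with Sgce (-0.27 ± 0.064) and Zrsr1 (-0.37 ± 0.091) lower over the list alone. The integrated stress and unfolded protein response had 0.001 with a mean of -0.009 (camera adjusted p = 0.935), with Atf5 (0.34 ± 0.077), Aldh1l2 (0.51 ± 0.14) and Psat1 (0.41 ± 0.11) higher and Creld2 (-0.28 ± 0.067) lower over the list alone. Inflammatory genes (0.062, camera adjusted p = 0.969), immediate early genes (0.002, with the test downward, 0.89) and RNA quality genes (-0.066, 0.741) had no member past over the list alone.

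Past the threshold of the averaged diet test were 5 of 17973 genes, Tfrc, Gypa and Slc11a2 upward and Cts6 and Tmcc2 downward, in edgeR. Just outside were Hemgn, Edaradd (-1.20 ± 0.19), Adcy1 (0.65 ± 0.11) and Kank3 (-0.30 ± 0.048), each at edgeR adjusted p = 0.0715, and Mfsd2a at 0.127. At an unadjusted p under 0.05 were 3244 genes, 1450 higher and 1794 lower, where chance gives 899. The tools differed in the count: DESeq2 called 231 (96 higher, 135 lower), limma-voom 5, limma with sample quality weights 4427, and edgeR without a filter on low counts 722. Without female IA 1 the count was 1751 (779 higher, 972 lower) and without male IA 1 it was 24, and these libraries held the lowest sample weights, 0.281 and 0.345. It was 3 without female ID 1, female ID 3, female IA 2, female IA 3, male IA 2 or male IA 3, and also 3 with the ribosomal repeat covariate. It was 339 without female IA 1 and male ID 1, and 4378 without these and male IA 1. By camera 16 of 36 lists passed, 11 upward and 5 downward, against 0 with an estimated correlation, 0 with fry and 10 after the length and GC correction.

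**Figure D2:**
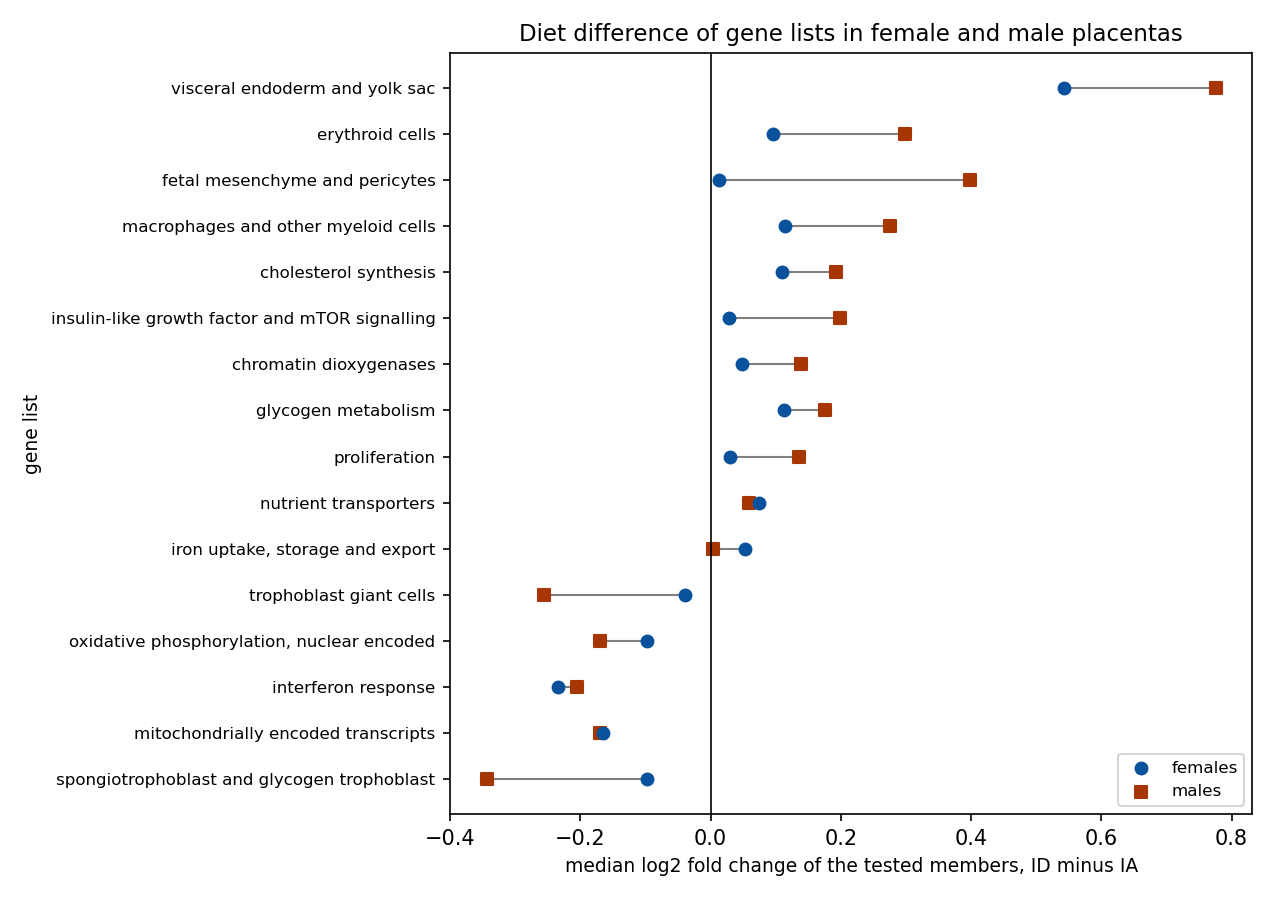
Median log2 fold change, ID minus IA, of the 16 gene lists past the camera threshold in the averaged contrast, with circles for females, squares for males and 1 row per list. Male medians lie further from 0 than female ones except for iron, nutrient transporter and interferon genes, for example 0.40 against 0.013 in mesenchyme.

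The next question was what the diet changed within each sex, since the titles divide it. In female placentas Tfrc (1.24 ± 0.18), Gypa (1.33 ± 0.19) and Slc11a2 (0.52 ± 0.075) were higher with an edgeR adjusted p = 0.0672 each, and did not pass. Tmcc2 (-1.01 ± 0.18, edgeR adjusted p = 0.316), Rhag (1.18 ± 0.25), Hemgn (2.169 ± 0.47), Cts6 (-0.96 ± 0.22), Edaradd (-1.11 ± 0.25), Crybg2 (-0.51 ± 0.12) and Vps72 (-0.32 ± 0.072, 0.863 as for the 5 before it) followed by unadjusted p and did not pass. EdgeR called 0 genes, with 1022 at an unadjusted p under 0.05 where chance gives 899, against 6 by DESeq2, 3 by limma with sample weights, 20 without a low-count filter and 2 without female IA 1. The count was 6 without female IA 1 and male ID 1, and 1361 without these and male IA 1.

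Female gene lists past camera were 12, with 0 at an estimated correlation (smallest adjusted p = 0.696) and 0 by fry. Lower were smooth muscle (median -0.21, camera adjusted p = 0.00019, interaction 0.54), with Actc1 (-0.60 ± 0.16) and Lmod1 (-0.39 ± 0.12), interferon response (-0.23, 0.000203), with Mx2 (-0.83 ± 0.33), oxidative phosphorylation (-0.097, 0.00231), mitochondrial transcripts (-0.17, 0.00681), spongiotrophoblast (-0.097, 0.0189), uterine natural killer cells (-0.27, 0.0189) and RNA quality genes (-0.48, 0.0295). Higher were cholesterol synthesis (0.11, camera adjusted p = 0.00219), with Insig1 (0.20 ± 0.081), iron (0.053, 0.00231), nutrient transporters (0.075, 0.00231), glycogen (0.11, 0.0234) and yolk sac genes (0.54, 0.0295). Only 5 passed without female IA 2, where spongiotrophoblast (camera adjusted p = 0.0708), yolk sac (0.333), oxidative phosphorylation (0.0681), mitochondrial (0.14), glycogen (0.169), cholesterol (0.0853) and RNA quality (0.169) calls were lost. Without female ID 3 the spongiotrophoblast median turned to 0.085 (camera adjusted p = 0.493), and natural killer (0.588), yolk sac (0.798) and mitochondrial (0.21) calls were lost. Without female IA 3 oxidative phosphorylation (median -0.003, camera adjusted p = 0.846), mitochondrial (0.13) and glycogen (0.14) calls were lost. Without female ID 1 iron (camera adjusted p = 0.0549), yolk sac (0.294), transporter (0.0698), glycogen (0.0698) and RNA quality (0.103) calls were lost, without female ID 2 natural killer (0.0774), glycogen (0.0519) and RNA quality (0.348) calls, and without female IA 1 the natural killer call (0.296). Smooth muscle and interferon calls stayed with each library left out in turn. The natural killer call also ended with 2 (camera adjusted p = 0.325) or 3 libraries left out (0.405), and the yolk sac call with 3 (0.0979). The RNA quality call ended with the ribosomal repeat covariate (camera adjusted p = 0.0555) and without hemoglobin and mitochondrial genes (0.0678). Over up to 14 alternatives the lowest camera adjusted p of these lists lay between 3.45e-10 and 0.00111 and the highest between 0.696 and 0.846. Of the other lists past in females alone, the interaction median was -0.076 for iron, -0.026 for nutrient transporters, -0.005 for mitochondrial transcripts, 0.14 for natural killer cells and 0.54 for RNA quality genes (camera adjusted p = 0.173, 0.392, 0.876, 0.295 and 0.0134).

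In male placentas Gypa, Tfrc and Slc11a2 were again among the genes with the smallest unadjusted p, and Tmcc2, Rhag and Hemgn were not. Gypa (1.31 ± 0.19), Cts6 (-1.34 ± 0.22), Tfrc (1.01 ± 0.17), Adcy1 (0.89 ± 0.15), Slc11a2 (0.43 ± 0.075), Kank3 (-0.36 ± 0.069), Slc35a1 (-0.36 ± 0.071), Pdcd10 (-0.44 ± 0.088), Kif14 (0.60 ± 0.12) and Laptm5 (0.88 ± 0.18) each had an edgeR adjusted p = 0.23 and did not pass. Over the mesenchyme list alone 5 rose, among them Col1a1 (0.95 ± 0.28) and Col6a1 (0.81 ± 0.20), and over the proliferation list alone 6 rose, among them Mcm2 (0.35 ± 0.10), and 1 fell. None of these 3 passed over all genes (edgeR adjusted p = 0.23). EdgeR called 0 genes, with 2940 at an unadjusted p under 0.05 where chance gives 899, against 65 by DESeq2, 1182 by limma with sample weights, 492 without a low-count filter and 2 without female IA 1. The count was 1 without female IA 1 and male ID 1, and 1775 without these and male IA 1.

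Male gene lists past camera were 13, with 0 at an estimated correlation (smallest adjusted p = 0.644) and 0 by fry. Lower were oxidative phosphorylation (median -0.17, camera adjusted p = 1.41e-08, interaction -0.095), spongiotrophoblast (-0.34, 8.28e-05), giant cells (-0.26, 0.000149, interaction -0.25), with Ctsq (-0.77 ± 0.20), and interferon response (-0.20, 0.0176). Higher were mesenchyme (0.40, camera adjusted p = 8.68e-07, interaction 0.42), cholesterol synthesis (0.19, 2.21e-05), yolk sac (0.78, 0.000742), growth factor signalling (0.20, 0.00118, interaction 0.19), proliferation (0.14, 0.00148), dioxygenases (0.14, 0.00386), myeloid genes (0.28, 0.00681), glycogen (0.17, 0.0219) and erythroid genes (0.30, 0.0476). Without male IA 1 the calls of spongiotrophoblast (camera adjusted p = 0.0575), giant cells (0.0723), myeloid (0.0562) and yolk sac genes (0.197) were lost. The erythroid call was lost without male ID 1 (camera adjusted p = 0.132), male ID 2 (0.462), male IA 2 (0.319) or male IA 3 (0.0603). The glycogen call was lost without male ID 2 (camera adjusted p = 0.0518), male ID 3 (0.0629), male IA 2 (0.153) or male IA 3 (0.101), and the interferon call without male ID 1 (0.132) or male IA 3 (0.107). Over 14 alternatives the lowest camera adjusted p of these lists lay between 5.83e-18 and 0.00207 and the highest between 0.644 and 0.76. Of the other lists past in males alone, the interaction median was 0.071 for proliferation, 0.10 for dioxygenases, 0.17 for myeloid and 0.033 for erythroid genes (camera adjusted p = 0.076, 0.173, 0.0609 and 0.329). With the ribosomal repeat covariate 7 of the 13 calls ended: yolk sac genes, with a median turned to -0.25 (camera adjusted p = 0.534), spongiotrophoblast (0.27), myeloid (0.248), glycogen (0.0963), interferon (0.534), dioxygenases (0.121) and growth factor signalling (0.37). The values of male ID 1 and male ID 3 for those repeats were the highest of all libraries. The length and GC correction ended the calls of giant cells (camera adjusted p = 0.0955), dioxygenases (0.465) and growth factor signalling (0.0902). With 2 libraries left out the erythroid (camera adjusted p = 0.195) and interferon (0.0994) calls ended. With 3 left out the erythroid (camera adjusted p = 0.202), spongiotrophoblast (0.168), giant cell (0.082), myeloid (0.208), yolk sac (0.694) and proliferation (0.152) calls ended.

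RNA quality genes did not pass as a list in males (median 0.29, camera adjusted p = 0.32). Over that list alone 3 rose, all chosen after their values were seen: Gm26917 (2.385 ± 0.75), Lars2 (1.78 ± 0.54) and Rn7sk (1.505 ± 0.46), with edgeR adjusted p = 0.238, 0.23 and 0.231 over all genes. With the ribosomal repeat covariate Lars2 turned to -0.36 and Rn7sk to -0.099.

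Whether the diet difference depended on fetal sex was tested by the interaction. No interaction of the iron genes passed: Tfrc had an interaction of -0.22 ± 0.24 and Slc11a2 -0.089 ± 0.11 (SE, edgeR adjusted p = 0.972 for both). No gene passed in edgeR, DESeq2 or limma, 697 had an unadjusted p under 0.05 where chance gives 899, and 13 passed in edgeR only without a low-count filter. By smallest p came Samd14 (0.62 ± 0.16), Gcnt1 (-0.40 ± 0.10), Bcl9 (0.43 ± 0.11), Tusc3 (-0.41 ± 0.11), Nt5c3 (-0.43 ± 0.11), Xlr5b (-0.69 ± 0.19), Gli2 (1.55 ± 0.42), Tmem30a (-0.32 ± 0.088), Akirin2 (-0.36 ± 0.10) and Tenm4 (1.40 ± 0.40), each at edgeR adjusted p = 0.972. Across the 17973 genes the female and male fold changes had a Pearson r of 0.373 and a Spearman rho of 0.383, and 65.2% had the same sign. The r was 0.167 without female IA 2, 0.189 without female IA 3, 0.22 without female ID 3 and 0.545 without female IA 1. By camera, a list test added after the data had been seen, 6 of 36 lists passed the interaction, 4 upward and 2 downward, against 0 with an estimated correlation and 0 with fry. They were 3 without female ID 2, 10 without male ID 2 or male ID 3, 11 without female ID 3 and 12 without male IA 2. The correlation r was 0.54 among genes of at least 10 CPM, 0.558 with 3 libraries left out and 0.181 with the ribosomal repeat covariate.

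The last comparison, of males with females, checked the labels and gave the size of the sex difference. Y-linked Ddx3y (8.01 ± 0.26, edgeR adjusted p = 2.83e-09), Uty (8.09 ± 0.32, 2.27e-08), Eif2s3y (7.54 ± 0.35, 9.11e-08) and Kdm5d (8.55 ± 0.53, 2.14e-05) were higher in males. The predicted gene Gm29650 (6.34, edgeR adjusted p = 0.0178), chosen after its values were seen, was higher as well. Lower in males were Xist (-5.50 ± 0.29, edgeR adjusted p = 3.28e-07), its antisense partner Tsix (-2.67 ± 0.29, 0.00151), Vamp7 (-0.46 ± 0.069, 0.034), which the annotation places on an unplaced scaffold, and Taf1 (-0.55 ± 0.083, 0.0363). Xist and Tsix overlap, so without strand their reads cannot be told apart. These 9 genes passed in edgeR, 5 higher and 4 lower, with 684 at an unadjusted p under 0.05 where chance gives 899, against 14 in DESeq2 and 24 without a low-count filter.

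X-linked genes of escape or of X inactivation, Xist and Tsix among them, had a median of -0.25 and a mean of -0.73 (camera adjusted p = 5.12e-16, or 0.000641 with an estimated correlation), and 8 fell over the list alone, Xist, Tsix and 6 others, such as Eif2s3x (-0.48 ± 0.098) and Pbdc1 (-0.26 ± 0.053). These list tests were added after the data had been seen. The cholesterol (0.08, camera adjusted p = 0.000191), yolk sac (0.29, 0.0103) and mesenchyme (-0.12, 0.0311) lists also passed, with adjusted p = 0.691, 0.865 and 0.865 at an estimated correlation. Among genes, Vamp7 kept its edgeR call only without male ID 3 and lost it without any other single library (adjusted p = 0.0566 to 0.163, within 1.44e-05 to 0.183 over 25 alternatives). Taf1 kept its call only without female IA 3 or male IA 1 and lost it in the other 10 (edgeR adjusted p = 0.0553 to 0.201, within 2.59e-07 to 0.201). Gm29650 lost it without male ID 1 (edgeR adjusted p = 0.0503), male ID 2 (0.0966), male ID 3 (0.0908) or male IA 3 (0.0764), within 2.59e-07 to 0.143 over 24 alternatives. With the ribosomal repeat covariate the edgeR calls of Vamp7 (adjusted p = 0.062), Taf1 (0.0578) and Gm29650 (0.062) ended, at log2 fold changes of -0.48, -0.58 and 6.39. With 2 libraries left out those of Vamp7 (edgeR adjusted p = 0.183), Taf1 (0.109) and Gm29650 (0.0578) ended, at -0.40, -0.52 and 6.497, and with 3 those of Vamp7 (0.128) and Gm29650 (0.0509), at -0.41 and 6.61.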

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

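The camera tests of the interaction and sex lists with all their settings, the 2 erythroid tests on cell number and shared reads, the length and GC correction, the ribosomal repeat covariate and the fits without 2 or 3 libraries were chosen after the data had been seen. The 6 results that follow were taken up because a test of the diet by sex interaction put them past its threshold, so that the diet difference differed between female and male placentas by camera with the preset correlation. With an estimated correlation none did (smallest adjusted p = 0.758), 1 list was under an unadjusted p of 0.05, and fry called 0.

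Mesenchyme and pericyte genes had an interaction median of 0.423 (female 0.013, male 0.399; camera adjusted p = 1.17e-07, or 0.895 with an estimated correlation, 1.62e-09 to 0.929 over 20 alternatives), with Col6a1 at 0.73 ± 0.27. Smooth muscle genes had 0.536 (female -0.209, male 0.144; camera adjusted p = 4.29e-05, or 0.758 with an estimated correlation), with Actc1 at 0.75 ± 0.23. Both calls stayed with each library left out in turn.

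Giant cell genes had -0.252 (female -0.04, male -0.256; camera adjusted p = 0.00745, 3.77e-05 to 0.929 over 20 alternatives), and the call was lost without female ID 2 (0.0933) or male IA 1 (0.28). The length and GC correction (-0.074, camera adjusted p = 0.614), the ribosomal repeat covariate (-0.164, 0.0747) and the fit without 3 libraries (-0.061, 0.567) ended it too. Oxidative phosphorylation genes had -0.095 (female -0.097, or -0.003 without female IA 3, male -0.17; camera adjusted p = 0.00149, 1.9e-09 to 0.929), and the call was lost without female IA 1 (0.566) or male IA 3 (0.614). It also ended with that correction (-0.035, camera adjusted p = 0.534), that covariate (-0.021, 0.346) and without 2 libraries (-0.018, 0.54). Growth factor and mTOR genes had 0.189 (female 0.028, male 0.198; camera adjusted p = 0.00745, 0.000507 to 0.998), lost without female ID 2 (0.0695), female IA 1 (0.0808) or male IA 3 (0.0792). Their call ended as well with the correction (0.06, camera adjusted p = 0.165), the covariate (-0.014, 0.998) and without 2 (0.055, 0.415) or 3 libraries (0.071, 0.0835).

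RNA quality and nuclear RNA genes had 0.536 (female -0.481, male 0.294; camera adjusted p = 0.0134, 6.41e-05 to 0.982 over 20 alternatives), lost without female ID 2 (0.146), male ID 3 (0.211), female IA 2 (0.0955) or male IA 1 (0.28). The ribosomal repeat covariate (-0.028, camera adjusted p = 0.982), the removal of hemoglobin and mitochondrial genes (0.297, 0.0738) and the fit without 3 libraries (0.487, 0.0835) ended the call too. Lars2, whose counts often follow ribosomal RNA, was at 2.27 ± 0.74 in the interaction (edgeR adjusted p = 0.972) and at -0.234 with the ribosomal repeat covariate. These genes were listed as markers of RNA quality and of nuclear RNA, so part of the interaction may come from the RNA and not the tissue: with that covariate 10 lists passed, of which 2 were among the 6. Of 100 drawn splits of the 12 libraries 85 gave as many lists as the real value of 6, with up to 17 and a median of 10 in the others, so chance cannot be excluded for this count. For the genes, all 100 gave at least the real count of 0, with up to 697.

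Nuclear oxidative phosphorylation genes were lower in ID placentas, by a median of -0.125. A bias of transcript length or GC content, as far as the correction captures it, is not the whole cause. After correction the median was -0.079, 63.3% of its size, with 56 of 75 members still negative (camera adjusted p = 0.000812, 6.68e-15 to 0.564 over 20 alternatives). That p used the preset correlation, and a bias that the correction missed cannot be excluded. Female IA 1, male IA 1 and male ID 1, which stand apart, are not the whole cause. Without them the median was -0.217. The same omission raised the count of called genes from 5 to 4378, so it was not a strict test. In females the median was -0.097, and -0.003 without female IA 3. A shift in the mix of tissues, for which yolk sac genes differed between libraries, stays open, as does a response to iron. With an estimated correlation the list gave adjusted p = 0.564, because its members move together from placenta to placenta.

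Cholesterol synthesis genes were higher in ID placentas, by a median of 0.163. After the length and GC correction it was 0.13, 79.7% of its size (camera adjusted p = 4.3e-06, 3.26e-07 to 0.564 over 20 alternatives). Without the 3 libraries it was 0.152 (camera adjusted p = 0.000253). Neither these libraries nor a length or GC bias, as far as the correction captures it, is the whole cause. With an estimated correlation the diet call of this list was lost (camera adjusted p = 0.564). The list was also higher in males than in females, by a median of 0.08 (camera adjusted p = 0.000191, or 0.691 with an estimated correlation). A shift in the mix of tissues and a response to iron stay open.

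Erythroid genes parted, with membrane genes higher and adult globins lower in ID placentas. More or fewer erythroid cells of an unchanged mix would move all of them alike. The same values that showed the pattern exclude this as the whole cause: of 32 members of the list, 13 rose and 7 fell over the list alone (edgeR). A change in the mix of primitive and definitive cells was not tested. If each read of near-identical globins was counted for a single copy, shared reads would move counts within a pair and leave its sum unchanged. Such a move cannot be the whole cause, since both members of each pair were lower in ID over the list alone. That also fixed the direction of the sums in advance. Whether such reads were dropped from both copies cannot be told from the sums. The summed CPM was lower in ID for both pairs, by -0.608 for Hbb-bs and Hbb-bt and -0.622 for Hba-a1 and Hba-a2 on the log2 scale (n = 6 per diet, exact permutation p = 0.00649 and 0.00433). A less mature erythroid population is a candidate explanation: the mean log2 CPM of 9 early minus 10 late genes was 0.158 higher in ID (-1.47 ± 0.078 against -1.628 ± 0.086, SD, n = 6 per diet, exact permutation p = 0.00866). It rested mainly on Klf1 (1.076 ± 0.279) and Sox6 (0.717 ± 0.177), and the late genes Slc4a1 (0.371 ± 0.147), Epb42 (0.438 ± 0.15) and Slc25a37 (0.369 ± 0.089) were positive too. The late genes Tent5c (-0.351 ± 0.084) and Isg20 (-0.388 ± 0.104) were negative, and the early genes Myb (-0.206 ± 0.128), Gata1 (-0.092 ± 0.094) and Epor (-0.036 ± 0.126) gave no direction (unadjusted p = 0.131, 0.343 and 0.781).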

How the results depend on the processing

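The fits without 2 or 3 libraries, the length and GC correction, the ribosomal repeat covariate and the list tests of the interaction and of sex, with every alternative, were chosen after the data had been seen. The cause of a moved value was not tested unless stated. Tfrc, Gypa and Slc11a2 passed in the averaged diet contrast under all 27 alternatives. Among the values of named genes, 1922 kept direction and side of the threshold under settings other than single omissions, 457 gained a call, 16 lost one and 19 reversed; for lists 224 kept both, 147 lost the call and 3 reversed.

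The averaged diet test called 5 genes in edgeR. It called 231 with DESeq2 (96 higher, 135 lower), 722 without a filter on low counts (368, 354), 4427 with sample quality weights (2277, 2150), 339 without female IA 1 and male ID 1, 4378 without these and male IA 1 (2259, 2119), and 3 with the ribosomal repeat covariate. DESeq2 and the weighted fit shared 231 genes, and the weighted fit and the fit without 3 libraries 3876. Weights and omission both act on the libraries with the largest spread, so their counts are not independent. Without 1 library the count ran from 3 (without female ID 1, for example) to 1751 (without female IA 1).

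In females 0 genes passed in edgeR (1022 at an unadjusted p under 0.05). It was 6 with DESeq2, 20 without a filter, 3 with weights, 6 without 2 libraries and 1361 without 3, and 0 to 2 with 1 library left out. In males 0 passed (2940 at an unadjusted p under 0.05), against 65 with DESeq2, 492 without a filter, 1182 with weights, 1 without 2 libraries and 1775 without 3, and 0 to 2 with 1 library left out. In females the fit without 3 libraries leaves 2 IA placentas, and in males 2 of each diet. For the interaction 13 passed without a filter, all higher, and 0 in edgeR under the others (697 at an unadjusted p under 0.05). For sex 9 passed, 14 with DESeq2 and 24 without a filter.

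Of 36 lists 16 passed for the averaged diet, 12 for females, 13 for males and 6 for the interaction. With an estimated correlation, and with fry, each of these counts was 0, since both allow for members moving together. The length and GC correction left 10 for the averaged diet, and the ribosomal repeat covariate gave 10 for the interaction. With 1 library left out the female count ran from 5 (without female IA 2) to 13, and the interaction count from 3 (without female ID 2) to 12 (without male IA 2). The sex lists were run with the preset and estimated correlations and fry only.

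The correlation of female and male fold changes, 0.373, was 0.54 among genes of at least 10 CPM, 0.492 without 2 libraries, 0.558 without 3 and 0.181 with the ribosomal repeat covariate. It ran from 0.167 (without female IA 2) to 0.545 (without female IA 1) with 1 library left out.

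These directions reversed. After the length and GC correction the mitochondrial list turned to 0.026 (camera adjusted p = 0.528, 3.02e-05 to 0.63 over its alternatives), mt-Nd3 to 0.026, Hamp to 0.134 and Flt1 to -0.071. With the ribosomal repeat covariate the male yolk sac list turned to -0.248, the interaction of growth factor and mTOR genes to -0.014, of Tfrc to 0.038 and of Lars2 to -0.234, Flt1 to -0.019, Epor to 0.054 and Synb to 0.163, and in males Lars2 to -0.363 and Rn7sk to -0.099. With 1 surrogate variable Flt1 turned to -0.063 and Synb to 0.157, and Synb was 0.001 by limma-voom. With weights Epor was 0.013. Slc39a14 was 0.019 with weights and 0.027 without 3 libraries, where the interaction of Tfrc was 0.118 and of Slc11a2 0.012; without 2 libraries that of Tfrc was 0.083. With 1 library left out Hamp ran from -0.154 to 0.087, Slc39a14 from -0.046 to 0.017, Epor from -0.094 to 0.058, Flt1 from -0.085 to 0.18 and Synb from -0.128 to 0.076. In females the spongiotrophoblast median ran from -0.39 to 0.085 and that of yolk sac genes from 0.056 to 0.95, where the camera direction turned without female ID 3 or female IA 2.

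Replicate numbers were shared by the groups, but the labels tie them to nothing. Of 18 pairs of same-numbered libraries 10 correlated over 0.1 (-0.389 to 0.395), and 10 of 12 libraries correlated best with their own number, a hint from the data and not the design. With the replicate block the averaged diet test called 210 genes (90 higher, 120 lower), of which DESeq2 shared 132, females 5 and males 0 in edgeR. With the replicate block within diet as a random effect (consensus correlation 0.358) it called 3, without Cts6 and Tmcc2. For sex the block gave 8 genes, without Vamp7 (edgeR adjusted p = 0.0637), and the block within diet 12, without Vamp7 (0.0616) and Gm29650 (0.143).

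Between TMM and the other edgeR scaling the median fold change moved by at most 0.00576. In simulated counts, where each gene had the same spread in all libraries, 16.4% of 1.5-fold interactions were recovered. Even there most differences of that size between the sexes were missed gene by gene. The real libraries differ in spread, so that share may not hold for them.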

Other observations

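The fit without female IA 1, male IA 1 and male ID 1, the cell type facts below and the structure of the largest split were chosen after the data had been seen. Among ID placentas Tfrc was at 1387 CPM or more, and among IA placentas at 876 CPM or less, with female IA 1 the lowest at 489.1 CPM. Afp was at 336.7 CPM in female IA 2, 490.8 CPM in female ID 2 and 4615 CPM in female ID 3, and Tpbpa ran from 4229 CPM in male ID 1 to 10860 CPM in male IA 3.

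Several genes near the threshold of the averaged diet test lay outside the iron, erythroid and trophoblast lists, and none of these passed. Edaradd, an adaptor of ectodysplasin signalling, was at 1.07 ± 0.338 CPM in ID and 2.47 ± 0.354 CPM in IA placentas (SD, n = 6), and Adcy1, an adenylate cyclase, at 5.41 ± 0.711 and 3.55 ± 1.06 CPM. Kank3, a gene of vascular cells, was at 39.0 ± 1.74 and 48.0 ± 2.34 CPM, and Mfsd2a, a carrier of lysophospholipids, at 66.6 ± 3.06 and 84.0 ± 7.40 CPM.

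Other splits of the 12 libraries were tested for each count. For the averaged diet test the real split gave 5 genes. Of 100 splits drawn from 200 possible ones 4, the real one included, gave as many, with up to 1649 in another split. A share this near to 0.05 from a partial draw cannot exclude chance. The split with 1649 genes set female IA 1 and male IA 1 with 4 ID placentas. These were female ID 1 and 2 and male ID 1 and 2. That split kept 8 of the 12 libraries on their own diet side. It may reflect a structure of the samples other than the diet, which was not tested. For the lists the real value was 16, and 4 of 100 splits, the real one included, gave as many. By the same reasoning chance cannot be excluded, and no single list was tested in this way. The highest other value was 19 and the median of the others 9. For sex the real value was 9 and the highest other 104, with 2 of 100 as large, the real one included. Y-linked genes and Xist fixed part of this count in advance, so the splits say nothing about the other called genes. For the correlation of female and male fold changes the real value was 0.373 and the highest other 0.584, with 7 of 100 as large, so chance cannot be excluded.

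Within a sex the 6 libraries make 10 splits, too few for a share under 0.05. In females the real count of genes was 0 and the highest other 0, as large in all 10, and for lists 12 and 17, as large in 5, with a median of 10 in the others. In males the real count of genes was 0 and the highest other 0, as large in all 10, and for lists 13 and 14, as large in 3, with a median of 9 in the others.

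Between pairs of libraries within a group the variance was 7.549 to 30.36 times that of counting error alone (chi-square per degree of freedom).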
